A study of Homo sapiens with 4 samples.

How the data were processed

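Gene expression was measured on 4 Illumina expression BeadChip arrays hybridised with biotin-labelled total RNA from MDA-231 cells, a human breast cancer line also written MDA-MB-231. Per the labels, RNA was taken 48 hours after a transient transfection with a plasmid carrying TARBP2 or GFP behind the CMV promoter, with 2 arrays per plasmid. The series' design text calls the control mock transfection, while the sample labels name the GFP plasmid, and the labels were followed. The groups and replicate numbers were read from the sample labels. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

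The deposited non-normalized intensity of each of 47323 probes is the mean bead brightness on a linear scale, without background subtraction. The deposited detection p-value beside it states how readily a background probe would be as bright, and within each array it fell with intensity with 0 exceptions. Another deposited table holds intensities that the authors had brought to the same quantiles on all arrays, on a linear scale, and each of its columns is a rising function of the matching non-normalized column. The submitters' processing notes name lumi, and its version is not given in the sources used here. The authors' final table holds, per the file headers, a log ratio of TARBP2 over GFP for each of 39747 sequence accessions and a class of down-regulated or background. That log ratio was treated as a log2 value deposited by the authors, and its class was down for 3353 accessions, all at a log ratio below -0.2. The final table has no column for single arrays and was not used for testing.

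The intensity tables name probes and the final table names sequence accessions, and no table used here pairs them directly. The pairs were recovered from the values. The authors' log ratio was found to equal the difference of group means of a single scaled inverse hyperbolic sine of the quantile-normalized intensities. An accession was tied to a probe where both values agreed to within 1e-09 and no other probe did, which held for 33114 accessions (83.3%), against 14 by chance in shifted tables. A further 1260 accessions were tied to a pair of probes whose mean matched to within 7e-10, against 59 by chance, and 5373 accessions were not tied. Pairs could be told apart mainly at large log ratios, so genes named through pairs are enriched for large changes. In simulated data 99.98% of single-probe accessions were tied to the right probe, and 972 of 973 accepted pairs were right. Accessions were matched without versions to gene symbols of the RefSeq annotation of GRCh38.p14, which gave a symbol to 22411 accessions and to 19311 probes of 16454 genes. That annotation served only for symbols and for the order of neighbouring genes. No probe sequences were used, so a probe that reads a relative of its gene was not detected.

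The intensities were background-corrected by normexp with background moments inferred from the detection p-values, offset by 16, quantile normalized and taken to log2 (neqc in limma 3.58.1 under R 4.3.3). Probes with a detection p under 0.05 on at least 2 of the 4 arrays were kept, which left 22123 probes, of which 11715 had a symbol. Each of 9951 genes was represented by its kept probe of highest mean level. Groups were compared with limma (lmFit and eBayes, 2-sided) with Benjamini-Hochberg adjustment over all genes, with 2 residual and 3.33 prior degrees of freedom, and genes at an adjusted p under 0.05 are said to have changed. Errors of log2 changes are standard errors (SE) of this fit, with n = 2 arrays per group. Where a gene was not above background on any array of a group, the fold is a lower bound. It sets the mean of the bright group against the mean, per array of the dim group, of the higher of the lowest detected level and the probe's own level.

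Before the data were examined, 22 gene lists were fixed, and the 21 with at least 5 genes tested were compared with all other genes by limma's camera at a preset correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over lists. Camera with a correlation estimated for each list, and fry, which tests whether a list moves 1 way on balance without reference to other genes, were run beside it. With an estimated correlation camera takes its p-values from the residual degrees of freedom, here 2, which leaves it little power whatever the correlation. Counts of list members are given with p-values adjusted over all genes and adjusted over the list alone. The genes named were also fixed by rule. They are TARBP2, APP and ZNF395, the 10 largest rises and 10 largest falls among changed genes whose groups did not overlap, leaving out placeholder symbols, and up to 4 genes of smallest p in each list. Any other gene named was chosen after its values were seen, and some genes that the rule names are not reported here.

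Windows of 50 neighbouring genes were formed along each chromosome, and their median log2 changes were compared with 1000 random gene orders. The alternatives were no background correction, scaling to the 75th percentile, the authors' quantile-normalized values, no or a stricter detection filter, the mean of a gene's probes, array weights, a trended robust prior, the replicate number as a block, leaving out each array, stricter thresholds and the other list tests. Added after the data were seen were the recovered scale of the authors, all detected probes, genes tied to 1 probe only, and removal of each window's median. In arrays simulated with the spread of the real fit over 9951 genes, the test recovered 36 of 50 genes changed by 1.5-fold, 44 of 50 by 2-fold, 50 of 50 by 4-fold and 49 of 50 by 8-fold. It also called 11 unchanged genes, 5.39% of its calls. Only these genes and the mitotic list were changed in the simulation, a far smaller share than the 56.8% called in the data. The recovery rates therefore need not hold for the real test. The number of arrays limits the precision. Probe pairing used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.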

Results

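Transcript levels were compared between MDA-231 cells given a TARBP2 plasmid and cells given a GFP plasmid, to find which transcripts differ when TARBP2, the double-stranded RNA-binding partner of DICER1, is raised. The set comprised 2 TARBP2 arrays and 2 GFP arrays, all from RNA taken 48 hours after transfection. The median raw intensity was 75.5 and 74.5 on the TARBP2 arrays and 78.5 and 78.7 on the GFP arrays. Between 44.1% and 45.9% of probes were detected on each array. Across genes, Pearson's r was 0.997 within each group and 0.954 between groups, where genes are not independent replicates. The standard deviation (SD) of log2 differences between arrays was 0.176 and 0.174 within the groups and at most 0.71 between them.

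TARBP2 itself was 256-fold higher on the TARBP2 arrays, at a log2 level of 15.12 ± 0.01 (SD, n = 2) against 7.12 ± 0.20 (SD, n = 2). The SE of this difference was 0.11 on the log2 scale, with an adjusted p of 3.77e-06. A second TARBP2 probe, tied to another transcript accession, did not pass the test in a fit over all detected probes (log2 change -0.22, adjusted p = 0.0722). Whether this probe lies within the plasmid's insert is not given in the sources used here.

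Of 9951 genes tested, 2854 rose and 2803 fell, so that 5657 (56.8%) changed. Here rose and fell mean higher and lower on the TARBP2 arrays than on the GFP arrays. The design cannot tell the plasmid apart from any other difference between the cells of the groups. At least 2-fold changes were found for 498 genes that rose and 431 that fell. Both arrays of a group lay on the same side of both arrays of the other for 7853 genes (78.9%), against 33.3% by chance. A total of 287 genes were detected on both TARBP2 arrays and neither GFP array, and 182 genes showed the opposite. The share that changed depended on the probes used. It was 50.6% of the 9020 genes on accessions tied to 1 probe. That restriction dropped genes named through pairs and moved others, such as APP, to dimmer probes. It was 40.3% of all 22123 detected probes, with or without a gene symbol. Both shares were computed after the data were seen.

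The largest rises on the TARBP2 arrays included RBM47, an RNA-binding protein, which was at least 24.7-fold higher and not above background on either GFP array. RNF144A, a ubiquitin ligase, was at least 20.8-fold higher, CD74, the invariant chain of MHC class II, at least 17.6-fold higher, and LAIR2, a secreted collagen-binding receptor, at least 12.3-fold higher. HSPA6 and HSPA7, heat shock genes of near-identical sequence, rose 26.1-fold and 20.2-fold. KRT81, a hair keratin, rose 19.3-fold from a log2 level of 8.96 ± 0.10 to 13.24 ± 0.03 (SD, n = 2 each). APCDD1L rose by 3.91 ± 0.18 on the log2 scale (SE), with detection on only 1 GFP array. Adjusted p-values of these genes lay between 3.77e-06 and 9.39e-05. NR3C1, the glucocorticoid receptor, was at least 177-fold higher by its brightest probe, while its other detected probe, tied to another transcript accession, was lower (log2 change -0.45, adjusted p = 0.04 over all detected probes). The call for NR3C1 thus rested on the choice of probe. Of 1539 genes with several detected probes, 17 had probes that changed in opposite directions.

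The largest falls were of EPB41L3, a membrane-skeleton protein, which was at least 86.3-fold lower and not above background on either TARBP2 array. MAGEC1, a cancer-testis antigen, was at least 32.7-fold lower, STXBP6 at least 31.0-fold lower and TMEM98 at least 30.2-fold lower. MMP1, interstitial collagenase, was 42.8-fold lower, with mean log2 levels of 6.04 and 11.46 (log2 change -5.42 ± 0.07, SE, n = 2 arrays per group). The secreted epithelial proteins AGR2 and TFF3 were at least 30.8-fold and 18.8-fold lower. Dimmer probes of AGR2 and TMEM98 had log2 changes of -0.65 and -1.53. They were not above background on either TARBP2 array, so the background level limits these values. PHACTR3, a phosphatase and actin regulator, was at least 21.6-fold lower, and NKX2-1, a transcription factor of lung and thyroid, at least 15.4-fold lower. CLDN1, a tight-junction claudin, was 19.6-fold lower. Adjusted p-values of these 10 genes lay between 3.77e-06 and 1.15e-05.

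**Figure D1:**
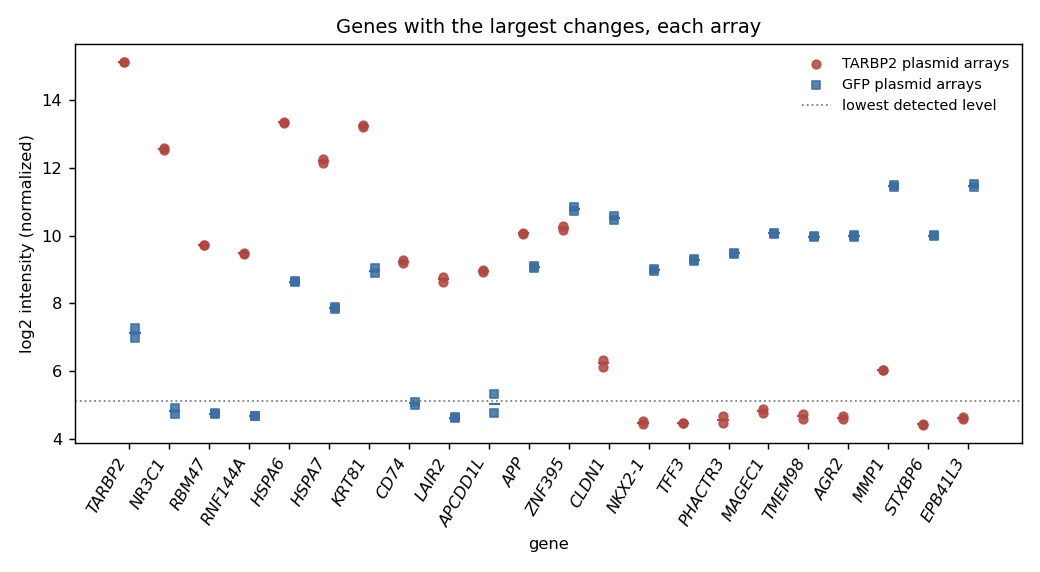
Normalized log2 intensity (vertical axis) on each array for TARBP2, APP, ZNF395 and the genes with the largest rises and falls (horizontal axis). Circles are the 2 TARBP2 arrays, squares the 2 GFP arrays, short bars the group means, and the dotted line the highest of the 4 arrays' lowest detected levels; TARBP2 stands at 15.12 against 7.12 and EPB41L3 at 4.61 against 11.47.

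APP, the amyloid precursor protein, and ZNF395, a zinc-finger protein, are transcripts that the study's published work is known to name as bound by TARBP2. If they were chosen on these samples, their values here are not independent evidence. The 2 moved in opposite directions here, and the direction that the published work gives for them was not compared. APP rose by 0.99 ± 0.07 on the log2 scale (SE, n = 2 arrays per group), or 1.99-fold, with an adjusted p of 0.000281 over all genes and 3.23e-05 adjusted over the list alone. All of its 3 detected probes were higher, with log2 changes of 0.58, 0.91 and 0.99. ZNF395 fell by 0.57 ± 0.08 (SE), with an adjusted p of 0.00342 over all genes and 0.00084 adjusted over the list alone. On accessions tied to 1 probe, APP was represented by its dimmer probe and the log2 change was 0.58.

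Among small RNA and double-stranded RNA factors, AGO2, the slicing Argonaute, fell by 0.80 ± 0.07 (log2, SE) and DGCR8, the partner of DROSHA, fell by 0.53 ± 0.07. AGO3 rose by 0.56 ± 0.07 (its other probe did not pass, at 0.36) and PRKRA, another double-stranded RNA-binding partner of DICER1, rose by 0.34 ± 0.07. Of 13 members tested, 2 rose and 3 fell, with the same counts adjusted over the list alone, and the list as a whole did not stand apart from other genes (median log2 change -0.05, adjusted p = 0.732). PRKRA lies in a window of chromosome 2 with a median log2 change of 0.27, and with window medians removed it no longer passed (adjusted p = 0.429). In the mRNA decay machinery, UPF2 rose by 0.84 ± 0.07 and CNOT8 by 0.50 ± 0.07, while EDC3 fell by 0.65 ± 0.08 and PARN, a poly(A)-specific ribonuclease, fell by 0.48 ± 0.08. Of 19 members, 2 rose and 6 fell, unchanged in number when adjusted over the list alone, and the list did not pass its test (median -0.10, adjusted p = 0.539). UPF2 lies in a window of chromosome 10 with a median of 0.44, and its log2 change was 0.41 with window medians removed.

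Interferon-stimulated genes were higher as a group on the TARBP2 arrays. Of 28 tested, 22 rose and 2 fell, or 23 and 2 adjusted over the list alone, with a median log2 change of 1.06 (camera adjusted p = 6.08e-07; adjusted p = 0.285 with an estimated correlation). IFIT1 and IFIT2, which bind foreign RNA and act in translation control, rose 3.70-fold and 2.89-fold. HERC5, the ISG15 ligase, rose 2.90-fold and OASL, an oligoadenylate synthetase relative, 2.95-fold. Among the members that fell was OAS1 (log2 change -1.10), an oligoadenylate synthetase, which was named after its value was seen. All 5 interferon and chemokine ligands tested rose, also when adjusted over the list alone (median 1.37, camera adjusted p = 0.00529; adjusted p = 0.338 with an estimated correlation). The list holds 10 genes, and without a detection filter its median was 0.28 over 9 genes (adjusted p = 0.00889). CXCL10, detected on only 1 GFP array, rose 4.47-fold, TNFSF10 (the death ligand TRAIL) 2.92-fold and CCL5 2.19-fold, while IFNL1, an interferon lambda, was at least 1.65-fold higher from below background. A dimmer CCL5 probe did not pass (log2 change 0.15, adjusted p = 0.336 over all detected probes). IFIT1 and IFIT2 lie on chromosome 10 and HERC5 and CXCL10 on chromosome 4, in windows of 50 genes whose median log2 changes were 0.39 and 0.43.

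Heat shock genes also rose as a group, with 10 of 12 members higher, or 11 adjusted over the list alone, and a median log2 change of 0.80 (camera adjusted p = 4.44e-05; adjusted p = 0.29 with an estimated correlation). HSPA6 rose by 4.70 ± 0.07 on the log2 scale and HSPA1A by 3.70 ± 0.07 (SE). HSPA1B rose by 1.91 ± 0.08 and the small heat shock protein HSPB1 by 1.27 ± 0.07. HSPA1A and HSPA1B have near-identical sequences, as do HSPA6 and HSPA7, so their separate values are uncertain. HSPB1 lies on chromosome 7 in a window with a median log2 change of 0.37.

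In the unfolded protein response list, DNAJB11 and SEL1L fell by 0.59 ± 0.07 and 1.04 ± 0.16, and XBP1 and DNAJB9 rose by 0.50 ± 0.07 and 0.47 ± 0.07 (log2, SE). Of 14 members 2 rose and 4 fell, the same adjusted over the list alone, and the list did not pass (adjusted p = 0.999), with a median of 0.04, a mean of -0.06 and a test direction of down. DNAJB9 lies in a window of chromosome 7 with a median log2 change of 0.47, and with window medians removed it no longer passed (adjusted p = 0.991). The log2 change of DNAJB11 was -0.31 with window medians removed. Targets of ATF4, the transcription factor of the integrated stress response, included PHGDH, an enzyme of serine synthesis, which fell by 1.79 ± 0.07, and the cystine transporter SLC7A11, which fell by 2.31 ± 0.19 and was detected on only 1 TARBP2 array. VLDLR and TRIB3 fell by 1.08 ± 0.11 and 0.60 ± 0.07. Of 20 targets, 3 rose and 11 fell, both over all genes and adjusted over the list alone, and the list did not pass (median -0.36, adjusted p = 0.0834). The test of this list passed without a detection filter (adjusted p = 0.0304), without replicate 1 of the TARBP2 arrays (adjusted p = 0.0426) and without replicate 1 of the GFP arrays (adjusted p = 0.047).

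Cholesterol biosynthesis genes fell as a group. Of 21 tested, 17 fell and none rose, or 18 adjusted over the list alone, with a median log2 change of -0.80 (camera adjusted p = 6.08e-07; adjusted p = 0.285 with an estimated correlation). HMGCS1, the synthase ahead of the rate-limiting reductase, fell by 1.75 ± 0.09 (log2, SE). FDFT1, squalene synthase, fell by 1.11 ± 0.07 and NSDHL, a sterol dehydrogenase, was 2.08-fold lower.

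Genes of hypoxia and glycolysis were mostly higher. Of 18 tested, 13 rose and 1, ALDOC, fell, the same adjusted over the list alone, with a median log2 change of 0.41 (camera adjusted p = 0.00828; adjusted p = 0.447 with an estimated correlation). NDRG1, a hypoxia-induced gene, rose 2.07-fold. ANKRD37 rose by 1.10 ± 0.08, PFKFB3, a regulator of glycolytic flux, by 0.86 ± 0.07 and the collagen hydroxylase P4HA1 by 0.79 ± 0.07. PFKFB3 lies in a window of chromosome 10 with a median log2 change of 0.44, and its change was 0.42 with window medians removed. Oxidative phosphorylation genes shifted less, with 10 of 22 higher and none lower, also adjusted over the list alone (median 0.22, camera adjusted p = 0.0092; adjusted p = 0.338 with an estimated correlation). ATP5MC3 rose by 1.12 ± 0.07, COX7B by 0.64 ± 0.08, UQCRH by 0.50 ± 0.07 and NDUFS5 by 0.45 ± 0.07. The log2 change of COX7B was 0.40 with window medians removed. Of 17 ribosomal protein genes, 3 rose and none fell, the same adjusted over the list alone, among them RPLP0 by 0.72 and RPL30 by 0.36 (list median 0.08, adjusted p = 0.579). RPS3 had a log2 change of -0.20 and an adjusted p of 0.0525. RPL30 lies in a window of chromosome 8 with a median log2 change of 0.30, and its adjusted p was 0.509 with window medians removed.

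**Figure D2:**
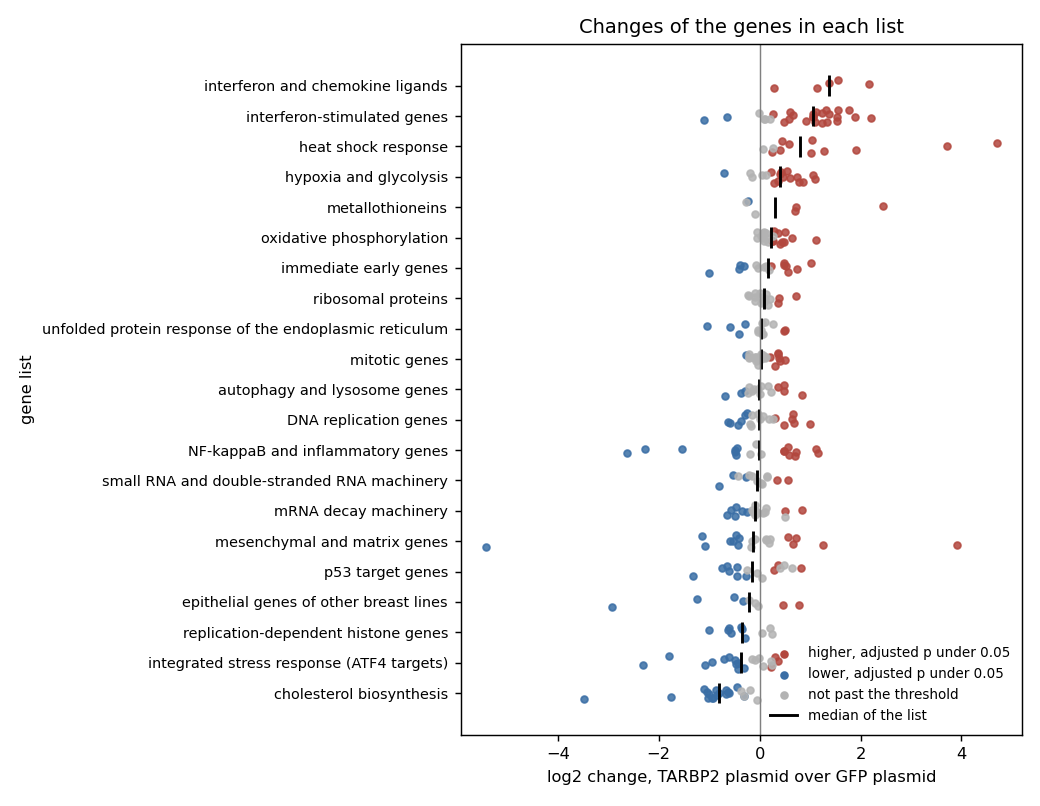
Log2 change, TARBP2 plasmid over GFP plasmid (horizontal axis), of each gene tested in the 21 lists with at least 5 genes (vertical axis, ordered by median). Red points rose, blue points fell and grey points did not pass the test; black bars are list medians, from -0.80 for cholesterol biosynthesis to 1.37 for the 5 interferon and chemokine ligands detected (0.28 over 9 genes without a detection filter).

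NF-kappaB and inflammatory genes moved in both directions. The chemokine CCL20 fell 6.17-fold, the cytokine IL1A, detected on only 1 TARBP2 array, 4.81-fold and TNFAIP3, an inhibitor of NF-kappaB signalling, 2.90-fold, while PTGS2, cyclooxygenase 2, rose 2.23-fold. Of 18 genes, 8 rose and 7 fell, or 8 and 8 adjusted over the list alone, with a median of -0.02 (adjusted p = 0.999). Among 16 targets of p53, a protein that is mutated in this line, TP53I3 fell by 1.33 ± 0.07, CDKN1A (the cell cycle inhibitor p21) by 0.74 ± 0.07 and ZMAT3 by 0.62 ± 0.07, while TP53INP1 rose by 0.81 ± 0.08. With window medians removed, the log2 changes of ZMAT3 and TP53INP1 were -0.34 and 0.51. In all, 3 p53 targets rose and 7 fell, or 3 and 8 adjusted over the list alone (median -0.15, adjusted p = 0.49). Of 16 immediate early genes, 7 rose and 4 fell, the same adjusted over the list alone (median 0.16, adjusted p = 0.49). FOS rose by 1.01 ± 0.07, MYC by 0.52 ± 0.07 and FOSB by 0.49 ± 0.07, and DUSP6, a phosphatase of ERK, fell by 1.01 ± 0.09.

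Gene lists of the cell cycle did not stand apart from other genes in the camera test. Of 20 DNA replication genes, 6 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.999), with a median of -0.01, a mean of 0.06 and a test direction of up. CCNE1, cyclin E1, rose by 0.99 ± 0.09 and UHRF1 by 0.69 ± 0.07, while the licensing factor CDT1 fell by 0.63 ± 0.07 and MCM5 by 0.59 ± 0.07. A dimmer UHRF1 probe, tied to another accession, did not pass (log2 change 0.11, adjusted p = 0.682 over all detected probes). With window medians removed, the log2 changes of UHRF1 and CDT1 were 0.40 and -0.41. Of 24 mitotic genes, 7 rose and 1 fell, or 6 and 1 adjusted over the list alone (median 0.03, adjusted p = 0.596). CDK1 rose by 0.51 ± 0.07, CCNA2 by 0.38 ± 0.07, KIF11 by 0.37 ± 0.07 and BUB1 by 0.37 ± 0.07. The windows around CDK1, CCNA2 and KIF11 had median log2 changes of 0.38, 0.38 and 0.39, and the windows' medians were taken after the data were seen. With the window medians removed, CDK1 had a log2 change of 0.13 (adjusted p = 0.196), CCNA2 of 0.0059 (adjusted p = 0.966) and KIF11 of -0.019 (adjusted p = 0.864). Of 10 histone genes, 7 fell, also adjusted over the list alone, where 2 more rose, and the list did not pass (median -0.36, adjusted p = 0.102), although it passed with window medians removed (adjusted p = 0.043). H1-2 fell by 1.00 ± 0.07, H2BC21 by 0.62 ± 0.07, H4C8 by 0.61 ± 0.07 and H2BC12 by 0.57 ± 0.10.

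Markers of cell identity changed in both directions. Of 20 mesenchymal and matrix genes, 5 rose and 8 fell, the same adjusted over the list alone (median -0.12, adjusted p = 0.611). COL6A3, a collagen VI chain, rose 15.0-fold and CDH11, a mesenchymal cadherin, 2.39-fold, while MMP1 and COL6A1, another collagen VI chain, fell 42.8-fold and 2.22-fold. Of 9 epithelial genes of other breast lines, 2 rose and 4 fell, the same adjusted over the list alone (median -0.22, adjusted p = 0.386). FOXA1, a luminal transcription factor, was at least 5.79-fold lower and CDH1, E-cadherin, at least 1.14-fold lower, the latter from near background on the GFP arrays. With window medians removed CDH1 no longer passed (adjusted p = 0.0836). KRT19 fell by 1.25 ± 0.08 and CLDN7 rose by 0.77 ± 0.08. Only 3 of 16 leukocyte genes were detected, too few for a list test, and CD14 and CD8A rose by 1.96 ± 0.11 and 1.49 ± 0.08 while CD2 fell by 0.65 ± 0.19, with the same 2 and 1 adjusted over the list alone. CD2 did not pass without either TARBP2 array (adjusted p = 0.12 and 0.137).

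Of 6 metallothioneins, MT1F rose by 2.45 ± 0.08 and MT1X by 0.70 ± 0.08, MT1M was at least 1.07-fold higher, and MT2A fell by 0.23 ± 0.07 (log2, SE). In all 3 rose and 1 fell, or 3 and 2 adjusted over the list alone (median 0.30, adjusted p = 0.539), and metallothioneins are close paralogs. MT2A did not pass with any 1 array left out (adjusted p from 0.0697 to 0.169). Of 16 autophagy and lysosome genes, 4 rose and 3 fell, or 4 and 2 adjusted over the list alone (adjusted p = 0.999), with a median of -0.0087, a mean of 0.03 and a test direction of up. The autophagy receptor SQSTM1 fell by 0.69 ± 0.07, and MCOLN1, a lysosomal channel, the protease CTSL and GABARAPL1 rose by 0.84 ± 0.11, 0.49 ± 0.07 and 0.48 ± 0.07.

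In all, 6 of the 21 lists passed camera with the preset correlation, and 16 passed fry, which does not compare a list with other genes. None passed camera with a correlation estimated for each list, where p-values rest on 2 residual degrees of freedom. There 3 lists had an unadjusted p under 0.05.

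Changes were not spread evenly over the genome. On chromosome 10, 238 of 406 genes rose and 40 fell, with a median log2 change of 0.38, and on chromosome 4, 184 of 369 rose and 58 fell (median 0.26). On chromosome 16, 62 of 446 genes rose and 174 fell (median -0.18), and on chromosome 9, 72 of 394 rose and 150 fell (median -0.12). The highest of 186 windows of 50 neighbouring genes lay on chromosome 7 between TPI1P2 and PRSS2, where 41 genes rose and 3 fell (median 0.70). The lowest lay on the X chromosome between HNRNPH2 and NDUFA1, where 33 genes fell and none rose (median -0.41). In 1000 random gene orders window medians lay between -0.34 and 0.38, and 11 windows were above this range and 2 below it. These chromosomes, windows and end genes were chosen after their values were seen.

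**Figure D3:**
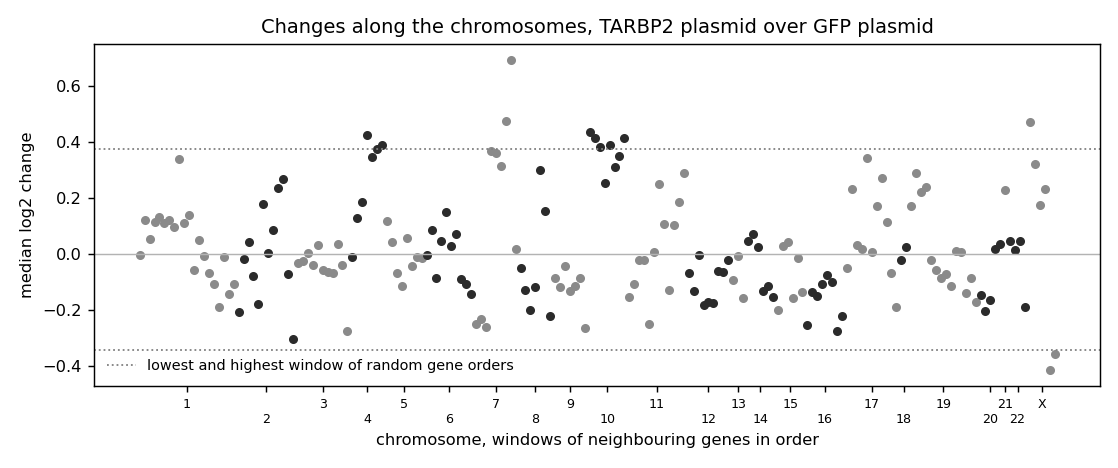
Median log2 change, TARBP2 plasmid over GFP plasmid (vertical axis), of 186 windows of 50 neighbouring genes in order along the chromosomes (horizontal axis; grey and black mark alternate chromosomes). Dotted lines are the lowest and highest window medians in 1000 random gene orders, -0.34 and 0.38; the windows range from -0.41 on chromosome X to 0.70 on chromosome 7.

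The authors' deposited table classed 2453 of the 9951 genes as down-regulated. Of these, 2322 fell in the limma test, 131 did not pass and none rose, while 481 genes fell here that the authors' deposited table did not class as down. The 2 sets of log ratios come from the same arrays, and probes were paired with accessions by matching the authors' log ratio. Agreement between the 2 sets was thus largely fixed by the pairing and is not independent support. Their Pearson r was 0.915 across genes, which are not independent replicates. The only DICER1 probe tied here was not above background, and the authors' deposited table lists a log ratio of 0.07 for its accession and of -0.31 for a DICER1 accession not tied to a named probe here.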

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

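The recovered scale of the authors, the fit of all detected probes, the restriction to accessions tied to 1 probe and the removal of window medians were chosen after the result was seen, and the other alternatives before. TARBP2, APP and ZNF395 kept direction and call under all alternatives run, with log2 changes of 3.89 (mean of its probes) to 8.18, 0.58 (accessions tied to 1 probe) to 1.01, and -0.64 to -0.44. The count of changed genes was 5692 to 6093 under the other scalings and 4433 to 4712 with 1 array left out, where the lone array of a group was assumed to vary like the other group. It was 929 (498 higher, 431 lower) for changes of at least 2-fold and 3744 (1809 lower) at an adjusted p under 0.01, both by construction. Testing all 22123 detected probes gave 8917 (4535 higher, 4382 lower). With window medians removed 4942 genes changed, among them 4275 of the 5653 placed genes that had changed in the same direction before.

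Of 21 lists, 0 passed with an estimated correlation, where p-values rest on 2 residual degrees of freedom, and 16 with fry, against 6. With the estimated correlation 3 had an unadjusted p under 0.05. Interferon and chemokine ligands kept too few genes for a test with a detection p under 0.01 on all 4 arrays, or with accessions tied to 1 probe. NR3C1 reversed to -0.45 under that detection filter, since its brightest probe was not detected on the GFP arrays. With window medians removed, DNAJB9 was at -0.0020 and KIF11 at -0.019, as their changes lay close to their windows' medians. PRKRA, CDK1, CCNA2, RPL30, CDH1 and MT2A no longer passed with that removal. CD2 also did not pass there (adjusted p = 0.0501), at a log2 change of -0.60 against -0.65, while histone genes passed (adjusted p = 0.043). Targets of ATF4 passed without a detection filter (adjusted p = 0.0304). MT2A also did not pass with any 1 array left out, nor CD2 without either TARBP2 array; the cause was not tested. Among single genes and lists, 1962 results under alternatives were on the same side of the threshold, 23 were lost, 21 gained and 3 reversed. The replicate number as a block gave 5455 genes. The correlation of same-numbered deviations was 0.0078, so no deviation shared by same-numbered arrays was seen. Whether they were handled together cannot be told from this. The alternative from the authors' final table could not be run, since it has no values per array. With 44.1% to 45.9% of probes above background, changes of dim genes are bounds, rest on levels near background or were not tested.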

Other observations

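The tests of the CDKN2A locus and of adjacent windows were chosen only after the result was seen, as was the removal of window medians. Among the genes detected in only 1 group, 8 were at least 8-fold higher on the TARBP2 arrays and 19 at least 8-fold higher on the GFP arrays. Rises were more common than falls along the later windows of chromosome 4, from USO1 to WWC2, where 32 genes rose and 7 fell in the first window (median log2 change 0.43) and 30 rose and 7 fell in the last (0.39). On the X chromosome the first window rose (median 0.47, 34 genes higher and 6 lower), while the window from ZBTB33 to TMEM185A fell (median -0.36, 4 higher and 27 lower). These windows were chosen after their values were seen.

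Of the 9951 genes tested 56.8% differed between the groups (40.3% of all detected probes). The normalization, dim probes, a regional bias and cells that differ in gene dosage were weighed. The lowest count under the other scalings was 5692 genes. Of these scalings, only that to the 75th percentile did not also bring the arrays to the same quantiles. It kept the calls of 5456 of the 5657 changed genes. Among the 3317 brightest genes 55.5% changed. These values argue against the quantile normalization or the detection limit as the whole cause. The variance of window medians was 0.0358, against at most 0.0088 in 1000 random gene orders and 0.000532 for replicate differences, and medians of adjacent windows correlated at 0.627, against at most 0.221, so a regional bias that acts between arrays of the same group is argued against. A candidate explanation for part of the pattern is that the groups were cells of different copy number over long stretches, as sublines or another line would be. With window medians removed 4275 of the 5653 placed genes that had changed were still changed in the same direction. Shifts shared equally by a window's genes therefore do not account for most of these calls. The removal takes out only what 50 neighbouring genes share. It cannot test differences of single genes between sublines or lines, nor copy number shifts to which a window's genes respond unequally. Of 5 probes of CDKN2A, CDKN2B and MTAP, a locus lost in MDA-MB-231 cells, 0 had a detection p under 0.01 on both arrays of a group or on any single array. The MTAP probe had one under 0.05 on both GFP arrays and neither TARBP2 array. Its highest log2 level was 5.19, near background. Its log2 change of -0.34 (limma, adjusted p = 0.0796 over all detected probes) is thus set against a background level. These probes cannot decide, so cells of another line that expresses the CDKN2A locus stay open. So do single-gene differences between sublines or lines, a batch or GC-related bias between the groups and an untested effect of TARBP2.

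The rise of heat shock genes was weighed against probes that read near-identical copies. Without HSPA1A, HSPA1B and HSPA6, the median log2 change of the other 9 members was 0.436, with 7 of them higher, which argues against near-identical copies as the whole cause. With window medians removed the median was 0.66 (camera with the preset correlation, adjusted p = 9.91e-05). Shifts shared equally by a window's genes therefore do not account for all of the median rise. The list's call before removal was lost in camera with an estimated correlation (adjusted p = 0.29). That estimate was -0.0084, below the preset 0.01, and the p-value rests on 2 residual degrees of freedom. A response to the TARBP2 protein or to its plasmid may underlie the rise, as may a stable difference between the cells of the groups, and the design has no further plasmid or untransfected array that could separate these.

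The rise of interferon-stimulated genes was weighed against a shift at a few loci. Without its 5 most changed genes the list's median log2 change was 0.917. As 22 of the 28 members tested rose, leaving out 5 could hardly lower the median far, so this step decides nothing. The count itself shows that the rise was not limited to a few genes. With window medians removed the list's median was 0.85 (adjusted p = 3.97e-06). Shifts shared equally by a window's genes therefore do not account for all of the median rise. The adjusted p of 3.97e-06 is from camera with the preset correlation. The list's call before removal was lost in camera with an estimated correlation (adjusted p = 0.285). That estimate was -0.036, below the preset 0.01, and the p-value rests on 2 residual degrees of freedom. The fall of OAS1, an interferon target, goes against a uniform rise of the pathway. A response to a difference in transfected nucleic acid, an effect of TARBP2 and a stable difference between cells may each underlie the pattern, and none of these was tested.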
